A study of Peltaster fructicola with 2 samples.

How the data were processed

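RNA of mycelium of Peltaster fructicola was sequenced in 2 libraries, 1 from potato dextrose and 1 from the apple surface, both at 15 days. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made by standard Illumina procedures. Per the submitters' processing notes, TopHat2 2.1.0, Bowtie and Cufflinks were used; which settings they had, and the genome build, are not given in the sources used here. The authors deposited 1 table with a value named FPKM (fragments per kilobase per library size) per gene and library, and the gene models, which per the file headers and source column were predicted with AUGUSTUS. The name of the deposited gene models also refers to hints given to the prediction, whose kind is not described here. Any scaling between libraries is not stated. The FPKM table holds 0 columns of samples outside the series, and 0 of its genes carry a name.

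The table gives a locus for each gene. Of the 5268 genes with more than 1 coding exon, the locus was exactly 1 exon of the gene model in 5266 and spanned a pair of exons in 2. That exon was the longest of its gene in 74.3% of cases, the last of a predicted transcript in the direction of transcription in 55.8% and the first in 29.6%. In the 2804 single-exon genes the locus was the whole model. Exons were counted here over all predicted transcripts of a gene, while the intron classes used the longest transcript, so 74 genes with a further transcript count as having more than 1 exon and as intronless. All loci matched exon borders of the gene models, so both files share coordinates, although they name the sequences differently. The values themselves went with the single exon, as read from multi-exon genes whose locus was under 85% of the coding length. Their apple products of FPKM and locus length lay within 0.15 of a whole number of steps in 79.5% of 396 cases. Products with the whole coding length did so in 13.6% of 250. That second share was partly fixed in advance, because the 85% limit alone carries a product of 1 step beyond 0.15. The 79.5% stands against the 30% that evenly spread values would give. Each value is therefore described as the level of 1 measured exon. The median locus was 944.5 bases and the median coding length 1254 bases. The gene model file held 0 rows for untranslated regions. Summed over loci, FPKM times length reached 93.0% of the sum that a whole library would give in the PDA library and 155.8% in the apple library, so the apple values are not scaled by the library's own fragments alone. Coordinates are 1-based, from the deposited gene models.

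Ratios were log2((apple + 1)/(PDA + 1)), with a pseudocount of 1 FPKM, over genes at 1 FPKM or more in at least 1 library. With 1 library per group no test was run, and a fixed rule of 2-fold was used. The step of the apple values, the product of FPKM and locus length that 1 fragment is worth, was the median of the products within 25% of the most frequent value (log10 bins of 0.02), over loci of 500 bases or more. Dividing by it gave implied fragments, with exact Poisson intervals at 95%. Those intervals leave out the error of the PDA value, whose fragments could not be counted. Shares of genes have Wilson intervals at 95%, and ratios of medians have bootstrap intervals from 2000 resamples of genes; both describe spread across genes, which are not replicates. Well covered loci were those of 500 bases or more whose implied apple fragments and PDA level at the apple depth had a mean of 20 or more. Loci chosen on the PDA library alone were those of 500 bases or more with a PDA level worth 20 or more apple fragments. The step, the intervals and both sets of loci were chosen after seeing the data.

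Gene classes (0, 1, 2, or 3 or more introns; 3 equal classes of coding length and of distance to the nearest gene), runs of 4 or more neighbouring genes, 1000 shuffles of gene order, the rule for named genes and the alternatives were fixed before the data were examined. The rule took, among genes at 10 FPKM or more in at least 1 library and with no names to be had, the 2 highest and 2 lowest ratios and runs by position. The 29 gene lists fixed at the same time (among them ribosomal proteins, carbohydrate enzymes, cutinases, transporters and melanin synthesis) were to be filled by product name or protein sequence. Neither was at hand, so 0 lists were evaluated.

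The code was tested on simulated data. Fragments were drawn for 5966 loci from the PDA levels at the apple depth, with 200 genes changed, and the step came back at 99.8% of its true value. The Poisson rule found 96.0% of genes raised 8-fold and 42.0% of genes lowered 8-fold, 46% of genes raised 2.83-fold and 10% of genes lowered 2.83-fold, and it called 0.0173% of unchanged genes. By value alone, 10.7% of unchanged genes came out at least 2-fold lower and 2.51% at least 2-fold higher. All 20 planted runs were found, but these were marked directly as higher genes with no fragments drawn. That checks the counting of runs and not how well runs are found at the apple depth. Alternatives were other pseudocounts, minimums, scalings, fold thresholds and run lengths. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.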

Results

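Gene expression was measured by RNA sequencing in mycelium of Peltaster fructicola, a dark fungus that grows on the surface of apple fruit. The samples were 1 library from mycelium kept on potato dextrose, a rich culture medium, and 1 from mycelium on the apple surface, both at 15 days. They are called the PDA library and the apple library here. The title of the series names a small, compact genome and life on the plant surface, and the comparison shows which genes differed in level between the 2 libraries. Each group held 1 library, so no difference has a replicate check and no p-value is given. Every count of genes below rests on a fixed rule of size and compares these 2 libraries, not the conditions.

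The deposited values are named FPKM (fragments per kilobase of the measured feature per library size; how the authors scaled them is not stated) for 8072 gene models on 5 chromosomes. Chromosome 1 held 2103 models, chromosome 2 held 1720, chromosome 3 held 1557, chromosome 4 held 1499 and chromosome 5 held 1193. The median gene was at 57.7 FPKM in the PDA library and at 35.8 FPKM in the apple library. In the PDA library 34 genes were listed at 0, against 1801 (22.3%) in the apple library, and 29 of them were at 0 in both. The gene models carry numbers and no names, so genes are described by position and structure.

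The apple library was much the shallower of the pair. For loci of 500 bases or more, the product of FPKM and locus length fell on even steps of 8088 FPKM x bases in the apple library, as it does when each step is 1 fragment. Of 1409 loci between 0.5 and 3.5 steps, 92.0% lay within 0.15 of a whole number of steps, where evenly spread values would give 30%. By this reading the apple values rest on 192596 fragments over all loci. Across the 5966 loci of 500 bases or more the median was 6 fragments, 3680 loci (61.7%) held fewer than 10 and 231 held 100 or more. No such steps were visible in the PDA library. Its lowest product above 0 was 166 FPKM x bases, which is 48.6 times below the apple step, and the next lowest was 46 times below it. If PDA fragments were counted whole, 1 PDA fragment was worth no more than that. By exact Poisson 95% intervals, a locus with 10 apple fragments is known only to between 4.80 and 18.4 fragments, and one with 100 to between 81.4 and 122 fragments. These intervals cover counting error only.

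**Figure D1:**
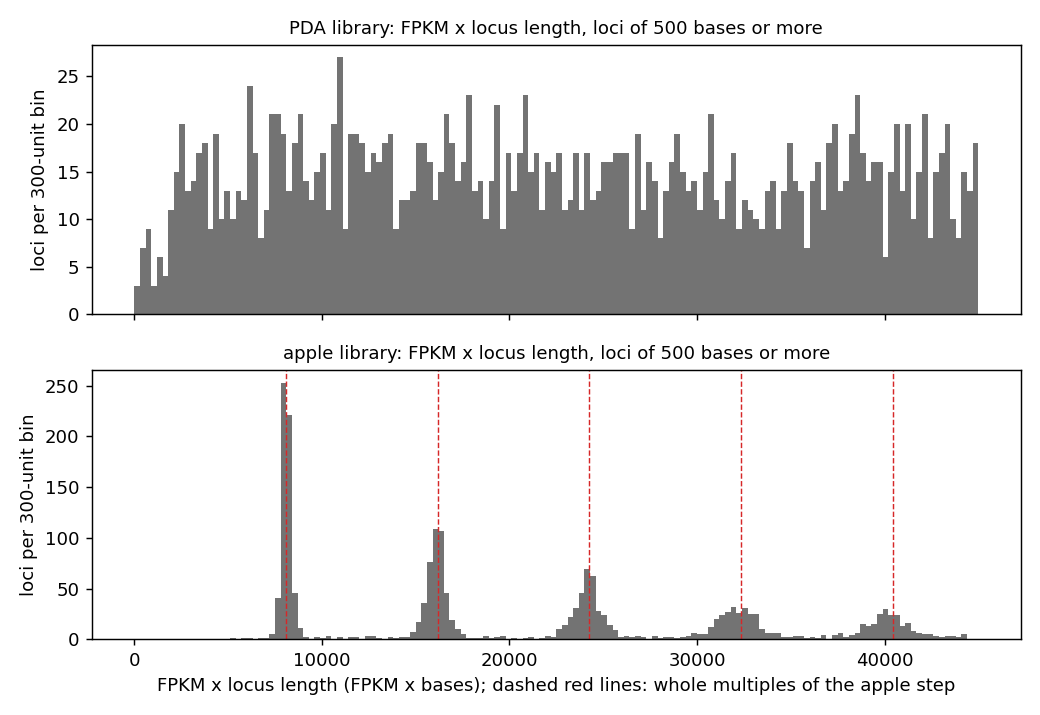
Histograms of FPKM times locus length for loci of 500 bases or more, with the PDA library above and the apple library below; the y axis gives loci per bin and the dashed lines mark whole multiples of 8088 FPKM x bases. The apple values gather at the multiples, while the PDA values show no steps of that size. The bins are wider than the lowest PDA product, so finer PDA steps could not show.

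Most genes seen on the apple surface were also seen in culture, and many genes seen in culture were missing from the apple library. At 1 FPKM or more, 8008 genes were detected in the PDA library and 6271 in the apple library. Both libraries shared 6255 of these genes, 1753 were detected in the PDA library alone and 16 in the apple library alone. All 1753 were listed at 0 in the apple library, and 1 fragment on a locus of ordinary length lies above 1 FPKM there, so a 0 in that library says that no fragment was drawn and not that the gene was silent.

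Levels in the 2 libraries were related but spread widely. Over the 8024 genes at 1 FPKM or more in at least 1 library, Spearman's rho was 0.52 and Pearson's r of log2(FPKM + 1) was 0.50; both are across genes, which are not independent replicates. On the log2(FPKM + 1) scale, 1595 genes (19.9%) were at least 2-fold higher in the apple library, 3662 (45.6%) were at least 2-fold lower and 2767 lay within 2-fold. At 4-fold the counts were 709 higher and 2560 lower, and 94 genes were at least 16-fold higher. This scale understates the change of genes at low FPKM. The median log2 ratio of genes at 1 FPKM or more in both libraries was -0.14. Relative to that median gene, 1767 genes were at least 2-fold higher and 3507 were at least 2-fold lower. Those 3507 include the 1753 lower genes listed at 0 in the apple library, which had no part in the median and which no scaling of that library can move.

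The balance of higher and lower genes changed with the rule and the scaling. Of the 3662 lower genes, 1753 (47.9%) were listed at 0 in the apple library. When the 95% Poisson interval of the implied apple fragments had to lie wholly beyond 2-fold from the PDA level, 705 of 5957 expressed loci of 500 bases or more were higher and 625 were lower. That rule finds lower genes less often than higher ones: in simulated data it found 46% of genes raised 2.83-fold and 10% of genes lowered as much. Among the 1342 loci with a mean of 20 or more implied fragments over both libraries, 549 (40.9%) were at least 2-fold higher in the apple library and 281 (20.9%) were at least 2-fold lower. The median log2 ratio of these well covered loci was 0.59 and their Spearman's rho was 0.19. Loci entered this set by the mean of both libraries, which a large change in a gene itself can raise. Choosing on that mean also lowers rho, so 0.19 cannot be set against the value over all genes. The direction in the well covered set also turned with the scaling. It held 426 higher and 354 lower on the TPM scale (median log2 ratio 0.16). With equal sums of FPKM times locus length in both libraries, it held 337 higher and 433 lower (median -0.15). The 1262 loci chosen on the PDA library alone leaned lower at the deposited scale. Across their intron classes, 14.5% to 17.8% were at least 2-fold higher and 42.4% to 44.6% at least 2-fold lower. Picking loci for high PDA values builds in an excess of lower genes, so neither set settles the direction.

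**Figure D2:**
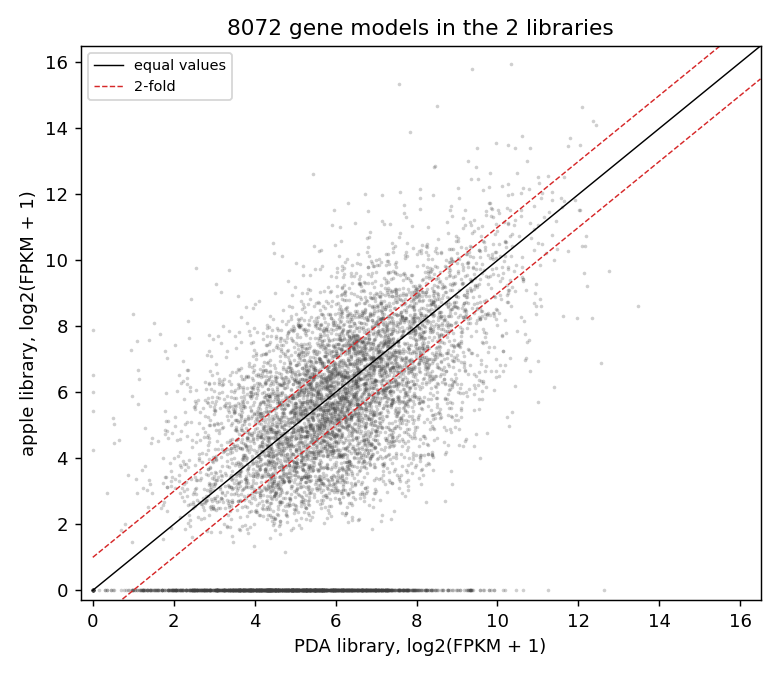
Each point is 1 of the 8072 gene models, with log2(FPKM + 1) in the PDA library on the x axis and in the apple library on the y axis; the solid line marks equal values and the dashed lines 2-fold. The row of points at the bottom holds the genes listed at 0 in the apple library, among them 1753 that reached 1 FPKM in the PDA library.

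A few genes took much of the apple library. The 100 highest genes held 42.3% of the summed FPKM in the apple library and 21.1% in the PDA library, and the 10 highest held 18.0% and 5.0%. The lists of the top 100 shared 37 genes, where independent lists would share 1.24. Of the apple library's top 100, 80 genes were at least 2-fold higher there than in the PDA library and 0 were at least 2-fold lower. Of the PDA library's top 100, 47 were at least 2-fold lower in the apple library, 18 were at least 2-fold higher and 4 were listed at 0. Each list was picked for high values in its own library, which builds such an excess in, so these counts show no difference between the libraries by themselves. The measured loci were under 500 bases for 53 of the apple list and 69 of the PDA list, and FPKM of short loci is the least certain.

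The gene with the most apple fragments lay on chromosome 2 from 2916675 to 2920547 on the plus strand, with a coding length of 3579 bases. It was singled out after its values were seen. It stood at 63799 FPKM in the apple library and 1285 FPKM in the PDA library, a ratio of 49.7 (95% Poisson interval of the apple fragments 49.0 to 50.3), or 29.7 when both libraries were given equal sums of FPKM times locus length. The last exon of its longest predicted transcript, from 2917508 to 2920547, was the measured locus. It held 23979 implied fragments, 12.5% of the implied apple fragments over all measured loci. The same exon held 0.420% of the PDA library's summed product of FPKM and length. A second such gene, on chromosome 5 from 2066122 to 2067897 on the minus strand, was at 56611 FPKM in the apple library and 660 FPKM in the PDA library. Its exon held 6698 implied fragments, or 3.48% of the implied apple fragments over all measured loci.

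By the rule fixed for named genes, g1137 and g6650 had the highest ratios and g1810 and g3365 the lowest. The first place of g1137 rests on the pseudocount: its log2 ratio was 7.90 with 1 FPKM, 11.2 with 0.1 and 5.598 with 5, where it ranked 13 of 7534 genes. Gene g6650 ranked 2 with 1 FPKM, 6 with 0.1 and 1 with 5, and g1810 and g3365 stayed the lowest pair with each. Gene g6650, on chromosome 3 from 347090 to 348433 on the plus strand, has 3 coding exons, and its last exon, from 347581 to 348433, was the measured locus. It stood at 42053 FPKM in the apple library and 189 FPKM in the PDA library, a ratio of 222 (95% Poisson interval of the apple fragments 216 to 229) that rests on 4435 implied fragments. That interval holds the deposited scale fixed, and with equal sums of FPKM times locus length the ratio was 133. Gene g1137, on chromosome 2 from 2751062 to 2751444 on the minus strand, was at 237 FPKM in the apple library and was listed at 0 in the PDA library. Its measured exon is 138 bases long, and 237 FPKM over that length is the worth of about 4 fragments by the step of longer loci. Gene g1810, on chromosome 4 from 224425 to 224734 on the minus strand, was at 6404 FPKM in the PDA library and was listed at 0 in the apple library. Its measured exon is 125 bases long. Gene g3365, on chromosome 1 from 383712 to 385282 on the plus strand, was at 2440 FPKM in the PDA library and was listed at 0 in the apple library, over an exon of 378 bases. No fold is given for these 3 genes because 1 side is 0. By the step of longer loci, the PDA values of g1810 and g3365 were 33.0 and 38.01 times the worth of 3 apple fragments.

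Genes with more introns were more highly expressed in both libraries, with introns counted in the longest predicted transcript of each gene. The median PDA level was 33.5 FPKM in the 2870 intronless genes, 61.6 FPKM in the 2345 genes with 1 intron, 92.4 FPKM in the 1464 genes with 2 introns and 132 FPKM in the 1345 genes with 3 or more. The median apple levels of the same classes were 22.7, 36.2, 54.7 and 79.9 FPKM. The ratio of the last class to the first was 3.95 in the PDA library (95% bootstrap interval over genes 3.55 to 4.29) and 3.52 in the apple library (3.01 to 4.08). Over all expressed genes the share at least 2-fold higher in the apple library did not follow the intron number. It was 20.5% in intronless genes (Wilson 95% interval 19.1% to 22.0%) and 19.9% in genes with 3 or more introns (17.8% to 22.1%). Among well covered loci it fell with each class, from 51.6% of 380 (46.6% to 56.6%) through 42.1% and 36.7% to 29.0% of 286 (24.1% to 34.5%). Among the 1262 loci of 500 bases or more chosen on the PDA library alone, at a level worth 20 or more apple fragments, it was 14.5% of 297 (10.9% to 18.9%) and 14.8% of 298 (11.2% to 19.2%), so the fall depended on how loci were chosen.

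**Figure D3:**
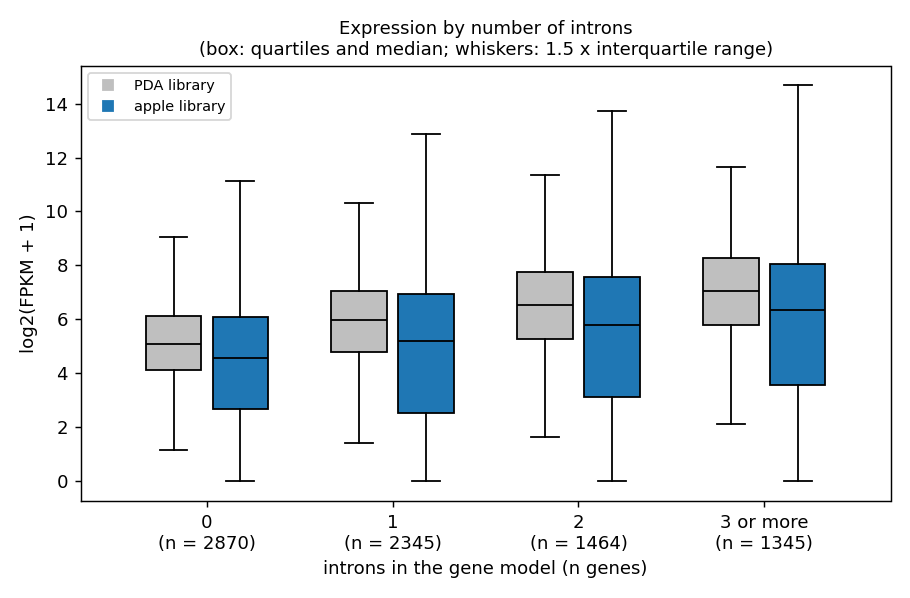
Box plots of log2(FPKM + 1) by number of introns for the 8024 genes at 1 FPKM or more in at least 1 library, with the PDA library in grey and the apple library in blue; boxes give quartiles and median, whiskers reach 1.5 times the interquartile range. The medians rise from 33.5 to 132 FPKM in the PDA library and from 22.7 to 79.9 FPKM in the apple library.

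Short genes were lower in the apple library more often than long genes. With genes placed in 3 equal classes of coding length, 56.7% of those up to 960 bases were at least 2-fold lower (Wilson 95% interval 54.8% to 58.6%), against 45.1% of the middle class and 35.0% of those over 1626 bases (33.2% to 36.9%). The share listed at 0 in the apple library was 37.2% in the short class and 8.51% in the long class, and a short locus draws fewer fragments at the same FPKM. Over all expressed genes spacing made a smaller difference. Genes within 175 bases of their nearest neighbour were at least 2-fold higher in 21.6% of 2678 cases (20.1% to 23.2%) and at least 2-fold lower in 43.3%. Genes more than 383 bases from any neighbour were at least 2-fold higher in 18.7% of 2670 cases (17.2% to 20.2%) and at least 2-fold lower in 49.0%. Among well covered loci the share higher was 47.4% of 439 near genes and 36.4% of 451 far genes. That gap was wider than between long and short coding lengths (41.7% and 36.2%). Among loci chosen on the PDA library alone the share higher was 16.9% of near genes (13.5% to 20.96%) and 13.7% of far genes (10.8% to 17.2%). There the gap between long and short coding lengths was the wider, at 18.5% and 12.4%.

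The chromosomes did not stand far apart. The share of genes at least 2-fold higher in the apple library ran from 18.1% on chromosome 3 (Wilson 95% interval 16.3% to 20.1%) to 21.2% on chromosome 2 (19.3% to 23.2%). The share at least 2-fold lower ran from 43.9% on chromosome 5 (41.1% to 46.7%) to 47.1% on chromosome 2 (44.8% to 49.5%).

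Under the main rule, though not under each alternative, genes higher in the apple library lay side by side more often than in shuffled gene orders. There were 20 runs of 4 or more neighbouring genes that were all at least 2-fold higher, 90 genes in all, where 1000 shuffles gave a mean of 9.81 runs and 4 shuffles gave as many. At 1.5-fold there were 36 runs against a mean of 28.9 in shuffles, and 98 of 1000 shuffles gave as many. At 4-fold there were 2 runs against a mean of 0.446, and 71 gave as many. Both miss a bar of 50, though 2 runs are too few to show that the excess was lost. Among well covered loci 740 gave as many, but there the next locus is seldom the next gene, so that count does not bear on neighbours. The 20 runs of the main rule measured 5.47 to 14.1 kb, lay on all 5 chromosomes, and 1 of the 20 held genes of a single strand. The longest held 6 genes, from 1210617 to 1220599 on chromosome 1, with apple values between 77.4 and 2208 FPKM and PDA values between 3.55 and 994 FPKM, and from 3610218 to 3623412 on chromosome 3, with apple values between 11.5 and 413 FPKM and PDA values between 3.84 and 169.7 FPKM. The run with the highest median ratio, 3.19 on the log2 scale, held 5 genes from 830211 to 841963 on chromosome 3. Some members of these runs rest on few fragments. Over loci of 500 bases or more, the lowest member held 6 implied fragments in the chromosome 1 run of 6 genes. It held 2 in the chromosome 3 run of 6 genes and 1 in the run of median 3.19. At such counts the Poisson interval need not lie beyond 2-fold. Runs of lower genes numbered 202, where shuffles gave a mean of 188.8 and 94 of 1000 gave as many. Of the 202, 189 held at least 1 gene at 0 in the apple library. The outcome for lower runs also varied with the rule. As many came from 0 of 1000 shuffles for runs of 3 or more, from 30 for 5 or more and from 39 at 1.5-fold. With the median ratio set to 0 it was 132, and at 4-fold 567. Well covered loci held 0 such runs, against a mean of 2.01 in shuffles. The correlation of each gene's log2 ratio with that of the next was 0.040 across genes, and 0 of 1000 shuffles reached it. These shuffles describe the 2 libraries and are not tests of the conditions.

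**Figure D4:**
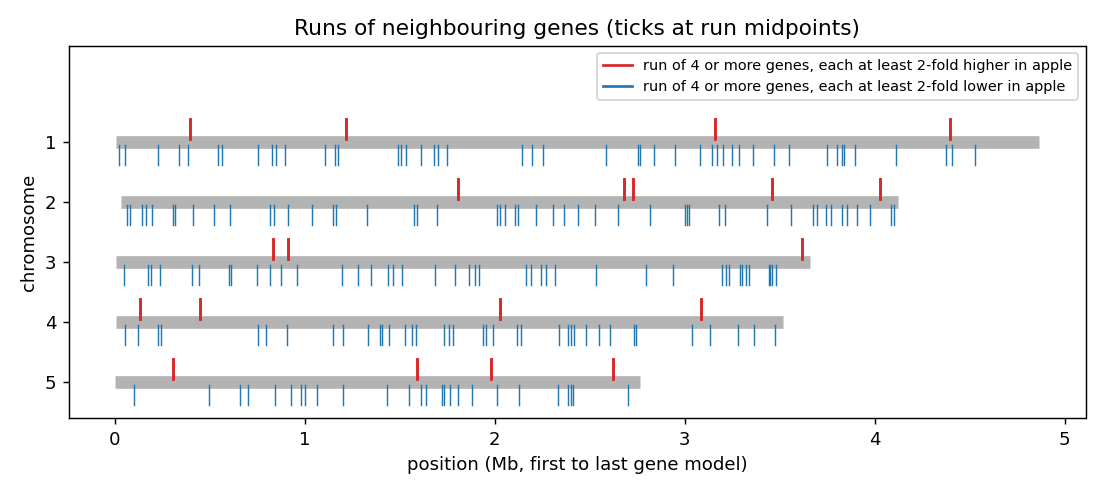
Map of the 5 chromosomes, drawn from the first to the last gene model with position in Mb on the x axis; ticks above a chromosome mark runs of 4 or more neighbouring genes each at least 2-fold higher in the apple library and ticks below mark runs at least 2-fold lower. The 20 runs of higher genes are spread over all 5 chromosomes, among 202 runs of lower genes.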

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

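No replicate could be left out, and no paired analysis was possible because each group holds 1 library. The gene lists were not run under any setting, for want of names. The alternatives with Poisson intervals, well covered loci, loci of 500 bases or more, equal sums of FPKM times locus length, or genes above 0 were chosen after seeing the data. Against 1595 higher and 3662 lower genes, 4-fold gave 709 and 2560, the Poisson interval 705 and 625, well covered loci 549 and 281, loci with a geometric mean of 20 or more implied fragments 467 and 180, well covered loci on the TPM scale 426 and 354, well covered loci with equal sums of FPKM times locus length 337 and 433, and leaving out genes at 0 in the apple library 1595 and 1909. The other settings kept both counts within 1.5 times; among them, loci of 500 bases or more gave 1220 and 2529, by leaving out genes, and rescaling each library to the same sum of FPKM (the TPM scale), a shift of -0.43 on the log2 scale, gave 1150 and 4159. Genes detected in the apple library alone numbered 5 at a minimum of 0.1 FPKM and 134 at 5 FPKM. The share of FPKM in the top genes was 14.5% and 33.6% for 50 genes and 30.0% and 51.6% for 200 genes, in the PDA and apple libraries. The intron ratio of apple medians was 3.0 at a minimum of 10 FPKM. Runs of higher and lower genes numbered 61 and 455 for 3 or more genes, 8 and 101 for 5 or more, 36 and 304 at 1.5-fold and 2 and 56 at 4-fold. Among well covered loci there were 20 runs of higher genes, against a mean of 21.9 in shuffles, and 0 runs of lower genes, and the correlation of neighbours was 0.018; there the next locus is seldom the next gene. Of the 100 recomputed counts for gene classes, 94 stayed within 1.5 times, and the 6 others came from leaving out loci under 500 bases, which removes genes: 167 higher and 362 lower with 2 introns, 131 and 278 with 3 or more, and 193 and 659 of short coding length. The share higher differed by -0.64 percentage points between 3 or more introns and none, by -22.6 among well covered loci and by -20.7 with the geometric mean; between near and far genes it differed by 2.97, 11.02 and 9.09 points. Loci chosen on the PDA library alone, also after seeing the data, gave 0.29 and 3.26. Depth limits the lower genes of the Poisson rule most: by that rule a locus with 0 apple fragments lies beyond 2-fold only if its PDA level is worth 7.38 fragments or more.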

Other observations

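Of the tests in this part, those of the no-change draws, of exon length, of shuffles within classes of locus length and of runs among well covered loci were chosen after the results were seen; the other shuffles and those of well covered loci by length, of exons covering most of the gene and of pair distance were set before their results.

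Neighbouring genes that converge had a correlation of log2 ratios of 0.063 (95% bootstrap interval over pairs 0.021 to 0.108), divergent neighbours 0.044 (0.003 to 0.081) and same-strand neighbours 0.020 (-0.013 to 0.054). The longest runs of lower genes held 11 genes each, on chromosome 1 from 2185689 to 2206032 and from 2940695 to 2962276, with 3 and 6 members at 0 in the apple library.

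The first pattern is the excess of genes lower in the apple library. Without the genes listed at 0 there, 1595 genes were higher and 1909 lower, so much of the excess lay in those zeros. Shallow sampling alone was tested by 1000 draws in which every locus of 500 bases or more kept its PDA level, scaled by 1.49 from well covered loci, at the apple depth. The draws gave at most 317 lower genes and the library held 2529, and at most 261 loci with no fragment against 1026. The scale of 1.49 comes from loci chosen on the mean of both libraries, and a larger scale gives fewer lower genes in the draws. With the deposited scale the highest of 200 draws were 718 lower genes and 408 loci with no fragment. Higher genes in the draws turned on the scale, against 1220 in the library. They numbered 135 to 194 at the deposited scale, 610 to 774 at 1.49 and 1518 to 1724 at 1.78, the scale of equal totals. How many higher genes sampling alone could give is therefore not settled. No smaller scale was drawn, so sampling at a smaller scale was not tested. The draws assume that each fragment is an independent molecule, so clumped losses from very little starting RNA, a library effect and a response to the apple surface may each account for the rest, and with 1 library per group they stay open. The share of lower genes also fell with locus length, by 23.1 percentage points between the shortest and longest of 5 equal classes against 6.33 in the draws at 1.49. Among well covered loci it still fell by 14.4 points (95% interval 6.97 to 21.9). That is above the 5 points that sampling was allowed in advance, though not wholly above the 10 set to exclude it. Draws there gave 0 points at scales of 1.49 and 1.78 and at most 0.95 at the deposited scale. This argues against sampling of independent fragments as the whole source of the trend among well covered loci. It does not settle the trend over all loci. Short loci need a higher FPKM to enter the well covered set, and other sources stay open.

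The second pattern is the higher level of genes with introns. If it came from measuring 1 exon per gene, it would fade where that exon is nearly the whole gene. The check took genes whose measured exon covers 80% or more of the coding length. There the ratio of median PDA levels, 1606 genes with introns in the longest model over 2870 without, was 1.73 (95% bootstrap interval 1.57 to 1.87). That lay above the bound of 1.2 set in advance, though it was smaller than the 2.47 over all genes. All intron numbers from 1 up were pooled, and their mix may differ from that of all genes. The check therefore does not bear on the rise with intron number. The length of the measured exon was tested in 5 equal classes of locus length, and the PDA ratio of 3 or more introns to none was 2.91 or more in each, which argues against it as the whole source in that library; the apple ratio was 2.62 or more in 4 classes and had no value in the shortest, where the intronless median was 0. A link between introns and transcript level is a hypothesis that these data allow, and other features of such genes, among them GC content and the accuracy of their models, were not tested. Whether the hints used to predict the models bear on which introns were called was not tested either.

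The third pattern is the runs of higher genes. Chance order was tested by shuffling within 5 classes of locus length, and 2 of 1000 shuffles held 20 or more runs, which argues against chance order under the main rule. The support varied with the rule: as many runs appeared in 1 of 1000 shuffles for runs of 5 or more, in 48 for 3 or more, in 37 with the median ratio set to 0, in 98 at 1.5-fold, in 71 at 4-fold and in 740 among well covered loci, where the next locus is seldom the next gene. Reads shared between close genes would make close pairs more alike, and the correlation was 0.0013 higher for pairs closer than 464 bases (95% bootstrap interval -0.040 to 0.049), so this source cannot be told apart from shared regulation because the interval spans the 0.03 set in advance. Gene clusters that respond to the apple surface are a candidate explanation that would need names and replicates.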
